A study of Oncorhynchus mykiss with 16 samples.

How the data were processed

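Liver RNA from juvenile rainbow trout (Oncorhynchus mykiss) was measured on a small 2-colour cDNA array. Each of the 16 arrays carried the RNA of 1 pool in one dye and, in the other, a common reference made from all experimental samples. Per the labels, the 4 pools of a group are biological replicates. With 1 array per pool, p-values rest on the spread between pools together with that between arrays, and the 2 cannot be separated. Dyes of sample and reference were assigned at random per array, per the series design, while the labels' protocol speaks of a swap on each array. The sources differ there, and the direction of every array rests on the dye recorded for its sample. Control and 10% samples were in Cy5 on 2 of 4 arrays each, 50% samples on 3 of 4 and 100% samples on 1 of 4. Per the labels' protocols, cDNA was made with aminoallyl dUTP and coupled to Cy3 or Cy5. The scanner and the image software are not given in the sources used here.

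The deposited scanner files give, per the file headers, the mean intensity of each spot and the mean intensity of its local background in Cy3 and in Cy5, with no subtraction and no dye normalization. Each array held 384 spots: 306 gene spots, 32 blank spots, 14 spots named Q and 32 spots named SSC. The 306 gene spots carried 152 gene IDs, of which 151 had 2 spots and ID 160 had 4. The gene IDs are plain numbers. The files do not pair them with gene names, and the reference table at hand has no such numbers, so genes are given by ID, without name, position or function. The 16 gene lists fixed before the data were examined (estrogen-responsive genes, heat shock proteins, xenobiotic metabolism, markers of other cell types and others) could not be matched to IDs, and the planned gene list tests were not run.

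The authors also deposited a table of log2 ratios per spot. Its construction was worked out from its values. On 302 gene spots its columns were compared with the loess residuals of uncorrected scanner signals, turned to sample over reference by the dye labels: the correlation was between 0.640 and 0.994 on 15 arrays and -0.560 on 10% replicate 4. Its direction is therefore read as sample over reference, with 1 array opposite to its dye label. A correlation does not fix the scale. It is taken as log2 from the slopes on the scanner values, which were 0.293 to 1.01 on those 15 arrays. Its cells were blank for 64 to 132 spots per array, on each array as many as the spots with a signal at or below background in either channel. The column medians were 0, -0.00409, -0.00735 and -0.00665 for control replicates 1 to 4, -0.000652, -0.00120, -0.00378 and -0.00621 for the 10% arrays, -0.00622, -0.00549, 0.00215 and -0.00432 for the 50% arrays, and -0.00820, -0.00285, 0.00597 and -0.00391 for the 100% arrays, so the columns are centred near 0. Why the slope on the scanner values fell to 0.293 on control replicate 3 and to 0.500 on control replicate 2 stays unknown. The table entered as an alternative. Its rows were matched by spot number. On the 302 gene spots the blank cells lay where the scanner signals put them in 4832 of 4832 cells, against 12 of 64 for the spots of ID 160 and 750 of 1248 for the control spots. The control spots of that table were not used, and the values of ID 160 were averaged over its 4 spots.

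From the scanner intensities, background was corrected with normexp (offset 50) and each array was normalized by loess (span 0.3) with weight 0 for the blank, Q and SSC spots, in limma 3.58.1 under R 4.3.3. Log2 ratios were turned to sample over reference by the dye labels, and the spots of a gene were averaged. All 16 arrays entered one fit with 4 group means and a dye term, so that differences are adjusted for the dye and can depart from those of plain group means. This left 11 residual degrees of freedom per gene (limma's prior added 3.01). Contrasts against control, the moderated F test over the 3 contrasts, the slope over effluent percent and the differences between concentrations were tested with lmFit and eBayes. Benjamini-Hochberg adjustment was over the 152 genes, within each comparison and not across the comparisons, with a threshold of 0.05. The normexp offset pulls ratios of dim spots towards 0, so folds of dim genes are understated.

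A gene was counted as above the blank spots in a channel where the mean signal over background of its spots exceeded the mean of the 32 blank spots by 3 SD. That rule was set after the files had been seen. Arrays with a median Cy5 background above 1000 were treated as a technical class: 7 arrays were in it, 2 control, 3 from the 10% group, none from the 50% group and 2 from the 100% group. The class was not uniform. Its control arrays and 100% replicate 4 were at 1598.5 to 1800.1, and its 10% arrays and 100% replicate 2 at 4401.7 to 5599.6. A single term for the class cannot adjust for that level, which goes with the group for control and 10% arrays. That class too was defined after the files had been seen, as were the alternatives built on it and on the deposited ratios without a dye term or with 10% replicate 4 turned, the turning of 10% replicate 4, the filter on the blank spots and the choice of the sample's channel for the filter at 2 times the background.

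Genes were named by a rule fixed before the data were examined. As the IDs have no names, it comes down to the 2 genes of smallest unadjusted p under 0.05 in each direction for each comparison against control, and the genes past the adjusted threshold for the trend and between concentrations. The fit was tested on simulated data: normal noise with each gene's residual SD and 30 of 152 genes changed, in 40 simulations per comparison. For the 10% comparison, 43% of genes changed by 0.5 on the log2 scale passed the adjusted threshold, 85.5% of those changed by 1 and 96.3% of those changed by 2; 0.656% of unchanged genes passed. For the 50% comparison the shares were 46%, 82.8% and 97.5%, and for the 100% comparison 41%, 84.3% and 98.8%. Of unchanged genes, 0.820% and 0.635% passed in these. The noise was independent between genes and held no effect of the Cy5 background class, and changes were added to processed ratios. The shares can therefore be higher than for real changes in dim genes. They also belong to 30 genes changed together. With fewer changed genes the adjusted threshold is stricter, and the shares would tend to be lower.

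Alternatives fixed before the data were examined were plain background subtraction with a floor of 1, no background correction, median centring, no dye term, a filter at 2 times the background in the sample's channel on 8 arrays, the deposited ratios, the replicate number as a block, array weights, a trended robust prior, fits of only 2 groups, equal spread between arrays, other dose scales, and leaving out each array. The median of repeated spots was not run, since it equals the mean for 2 spots, and slide and scan date were not used here. The replicate numbers are in the labels of every group; deviations of same-numbered arrays from their group and dye means correlated at 0.0546 on average over 24 pairs, between -0.231 and 0.399, with 9 pairs above 0.1, so the numbers were not taken to pair the samples.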

Results

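Juvenile rainbow trout were exposed on site to municipal wastewater effluent at 10%, 50% or 100%, or kept upstream as the control (0%). The transcript levels of 152 genes in whole liver were compared between the 4 groups. Each group held 4 independent pools, given as biological replicates, and each pool had 1 array. The question was whether hepatic transcript levels differed between the control and each concentration, and whether they changed with concentration. The genes are known here by array ID only.

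Signals were dim. The median gene spot stood at 1.03 to 1.12 times its background in Cy3 and at 1.02 to 1.16 times in Cy5, and between 1 and 30 of the 306 gene spots per array exceeded 2 times the background in both channels. Between 11 and 114 of the 152 genes per array, with a median of 44, were above the blank spots in both channels. The share was 29.9% ± 8.69 in control (SD, n = 4), 27.5% ± 17.5 in the 10% group (SD, n = 4), 53.8% ± 19.9 in the 50% group (SD, n = 4) and 32.4% ± 25.1 in the 100% group (SD, n = 4). Only 5 genes were above the blanks in both channels on all 16 arrays, 50 were so on at least 8 arrays, and 22 on none. The 2 spots of a gene differed by a median of 0.15 to 0.35 on the log2 scale within an array, and correlated across genes, which are not independent replicates, at 0.157 to 0.695. The number of arrays limits the precision. A group difference had a median standard error of 0.18 on the log2 scale for each concentration against control, and the half-width of its 95% interval had a median of 0.39. Differences and folds are those of the fit with its dye term, so they need not equal the difference of the 2 means printed beside them.

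**Figure D1:**
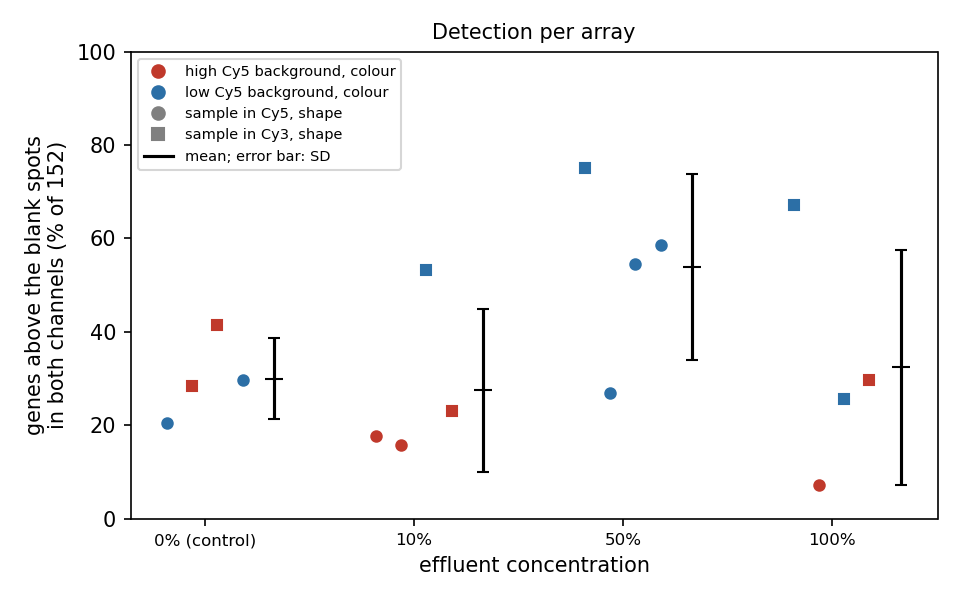
Percent of the 152 genes above the blank spots in both channels (vertical axis) for each array, by effluent concentration (horizontal axis); points are arrays, coloured by Cy5 background and shaped by the dye of the sample, with the group mean and SD beside them. The 16 arrays ranged from 7.24% to 75%, and the 50% group, which held no array of high Cy5 background, had the highest mean at 53.8%.

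In the livers of the 10% group, genes 178 and 131 had the smallest p among genes with a higher level than in control, and genes 144 and 26 among those with a lower level, but none of the 152 genes passed the adjusted threshold. Gene 178 averaged 0.50 ± 0.27 against -0.30 ± 0.52 in control (log2 ratio to the pool, SD, n = 4 each), a dye-adjusted difference of 0.80 (SE 0.23), or 1.74-fold, with an adjusted p of 0.519 by limma. It was above the blank spots in the sample's channel on 2 of the 4 arrays of the 10% group and 1 of the 4 control arrays. Gene 131, above the blanks on all 4 arrays of both groups, averaged 0.63 ± 0.83 against -1.14 ± 1.12 in control, a dye-adjusted difference of 1.77 (SE 0.65). With median centring in place of loess that difference was 4.09 and passed, with an adjusted p of 0.0123, against 0.873 at most over its alternatives. Gene 131 is among the 7 genes over 2 times the background, whose mean leaned towards Cy5 with median centring alone. A dye bias can therefore enter the value of 4.09. Gene 144, also above the blanks on all of these arrays, averaged -0.70 ± 0.96 against 0.99 ± 1.91, a dye-adjusted difference of -1.69 (SE 0.64) that was -1.05 without control replicate 3. Gene 26 averaged -0.13 ± 0.41 against 0.29 ± 0.09, a dye-adjusted difference of -0.42 (SE 0.17) that was -0.25 without 10% replicate 1 and -0.98 with median centring, and it was above the blanks on 2 arrays of the 10% group and 1 control array. By limma, 11 genes had an unadjusted p under 0.05, 5 higher and 6 lower, where 7.6 are expected by chance, and the smallest adjusted p was 0.519. That count was 4 without 10% replicate 1, 5 without control replicate 4, 7 without control replicate 1 and 20 without 10% replicate 4. The direction of 10% replicate 4 is in doubt, since the deposited ratios run opposite to its dye label. With that array turned, 20 genes had an unadjusted p under 0.05, the smallest adjusted p was 0.0546 and no gene passed. The differences of genes 178, 131, 144 and 26 were then 0.44, 2.11, -1.24 and -0.59, and of the 4 only gene 131 was still among the 2 genes of smallest p in its direction. Over their alternatives the 4 differences ranged from 0.07 to 2.31, 0.75 to 4.09, -2.48 to 1.77 and -1.88 to -0.09. With control replicate 2 left out, gene 178 alone passed, at 1.02 with an adjusted p of 0.0349, against 0.936 at most over its alternatives. That array is the only control array on which gene 178 was above the blank spots, so this pass rests on control values not above them. The sign of gene 144 turned with median centring in place of loess (1.77). Among the arrays of low Cy5 background alone it was 0.28, a value that rests on 1 array at 10% and 2 control arrays.

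At 50% effluent, genes 73 and 77 had the smallest p among higher genes and genes 69 and 129 among lower ones, and no gene passed the adjusted threshold. Gene 73 averaged 0.34 ± 0.39 against -0.32 ± 0.48 in control (SD, n = 4 each), a dye-adjusted difference of 0.76 (SE 0.23), or 1.70-fold, with an adjusted p of 0.683 by limma. Gene 77 averaged 0.31 ± 0.33 against -0.25 ± 0.29, a dye-adjusted difference of 0.59 (SE 0.20). Genes 73 and 77 were above the blanks on all 4 arrays of the 50% group, and on 3 and 2 control arrays. Gene 69 averaged -0.78 ± 0.43 against -0.27 ± 0.22, a dye-adjusted difference of -0.56 (SE 0.21), and gene 129, above the blanks on 1 array of each group, averaged -0.34 ± 0.38 against 0.33 ± 0.67, a dye-adjusted difference of -0.66 (SE 0.30) that was -0.23 without control replicate 1. By limma, 5 genes had an unadjusted p under 0.05, 3 higher and 2 lower, and the smallest adjusted p was 0.683. That count was 2 without 50% replicate 4, 8 without 50% replicate 1, 9 without 50% replicate 3 or without 10% replicate 4, and 10 without control replicate 4, and 8 with 10% replicate 4 turned. Over their alternatives the differences of genes 73, 77, 69 and 129 ranged from 0.32 to 1.13, 0.09 to 1.48, -0.73 to -0.27 and -2.30 to -0.07. With the authors' deposited ratios gene 73 alone passed, at 0.35 with an adjusted p of 0.0465, against 0.991 at most over its alternatives.

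At 100% effluent, genes 174 and 178 had the smallest p among higher genes and genes 144 and 121 among lower ones, and no gene passed. Gene 174 averaged 0.11 ± 0.28 against -0.17 ± 0.09 in control (SD, n = 4 each), a dye-adjusted difference of 0.33 (SE 0.13), or 1.26-fold, with an adjusted p of 0.797 by limma. It was above the blanks on 2 arrays of the 100% group and 1 control array, and its difference was 0.18 without 100% replicate 2. Gene 178 averaged 0.33 ± 0.42 against -0.30 ± 0.52, and its dye-adjusted difference of 0.55 (SE 0.23), which was 0.36 without control replicate 3, uses the same control arrays as the one at 10%. Gene 144 averaged -0.36 ± 1.33 against 0.99 ± 1.91, a dye-adjusted difference of -1.74 (SE 0.65) that was smaller, at -1.004, without control replicate 3. Gene 121, which was above the blanks on all 4 arrays of both groups, averaged -0.35 ± 0.72 against 1.54 ± 0.91, a dye-adjusted difference of -2.18 (SE 0.96). By limma, 6 genes had an unadjusted p under 0.05, 3 in each direction, and the smallest adjusted p was 0.797. That count was 2 without control replicate 4 or without 100% replicate 2, and 3 without control replicate 3. With 10% replicate 4 turned, gene 178 was no longer among the 2 higher genes of smallest p. Over their alternatives the differences of genes 174, 178, 144 and 121 ranged from 0.02 to 2.50, 0.15 to 1.95, -3.22 to 1.64 and -2.72 to 1.09. The signs of genes 144 and 121 turned with median centring in place of loess, to 1.64 and 1.09. Gene 144 was at 1.25 among the arrays of low Cy5 background alone, which hold 2 arrays of each of these groups.

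**Figure D2:**
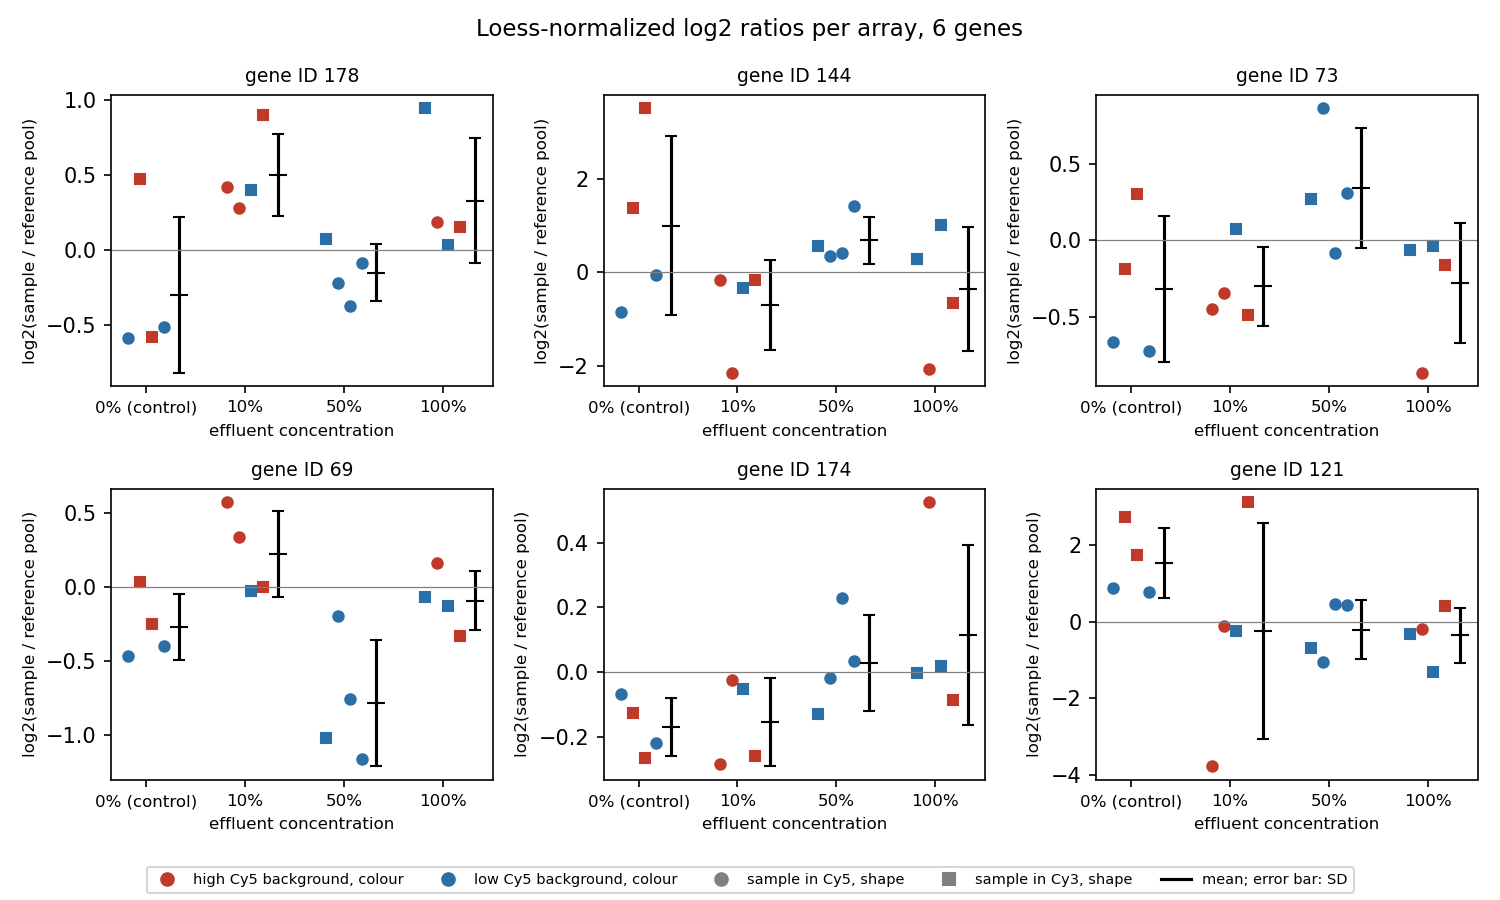
Loess-normalized log2 ratio of sample to reference pool (vertical axis, a scale of its own per panel) by effluent concentration (horizontal axis) for genes 178, 144, 73, 69, 174 and 121, those of smallest p in each direction of each comparison against control and those whose sign turned with the processing; points are arrays, with the group mean and SD beside them. Gene 69 lies between -1.17 and -0.20 on the 50% arrays and between -0.02 and 0.58 on the 10% arrays, and gene 144 between -0.85 and 3.50 on the control arrays.

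The order of the concentrations was tested with a slope. No gene passed the adjusted threshold for a linear trend over 0, 10, 50 and 100% effluent in limma, with 7 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.897. That count was 0 without 100% replicate 2, 3 without 10% replicate 4 or with it turned, and 4 without 100% replicate 3. Gene 174 had a slope of 0.34 log2 units per 100 percentage points, with an adjusted p of 0.897. Over the 3 contrasts together, limma's F test passed no gene, with 6 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.189. That count was 11 without 50% replicate 1, 13 without 10% replicate 3, 15 without 10% replicate 4 and 14 with it turned, and without 50% replicate 2 gene 69 passed with an adjusted p of 0.0205.

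Between concentrations, 1 gene passed, the only pass of the main fit in any comparison. The p-values were adjusted within each comparison and not across them, so this pass is not corrected for the number of comparisons. Gene 69 was lower at 50% than at 10% effluent, at -0.78 ± 0.43 against 0.22 ± 0.29 (SD, n = 4 each), a dye-adjusted difference of -1.05 (SE 0.21), or 2.08-fold lower, with an adjusted p of 0.0226 by limma. It was above the blank spots on all 4 arrays of the 50% group and on 2 of the 4 arrays of the 10% group. Those 2, replicates 3 and 4, were at -0.02 and -0.00044, while replicates 1 and 2, the 2 arrays with the sample in Cy5, where it was not above the blanks, were at 0.58 and 0.34. The fold therefore rests in part on values not above the blanks. In the same fit, gene 69 differed from control by 0.49 (SE 0.20) at 10%, by -0.56 (SE 0.21) at 50% and by 0.23 (SE 0.21) at 100%, and none of these passed the adjusted threshold. The difference between 50% and 10% kept its sign in all 33 alternatives that gave a value, from -1.56 to -0.47. It passed in 16 of them, several of which only leave out a control or 100% array, outside this difference. It did not pass when 10% replicate 1, 10% replicate 2, or 50% replicate 1, 3 or 4 was left out, where the adjusted p was 0.154, 0.108, 0.134, 0.0753 and 0.0811; with each array left out in turn the difference was between -1.23 and -0.92. The Cy5 background class was spread unevenly over these groups, with 3 of 4 arrays at 10% and none at 50%. With the class as a block the difference was -0.90 and the adjusted p 0.358 by limma. A block shifts Cy5 and Cy3 samples alike, so it cannot remove a bias that turns with the sample dye. With a dye term for each class, gene 69 did not pass either. On arrays of high background, gene 69 was at 0.58, 0.34 and 0.16 with the sample in Cy5. With the sample in Cy3 it was at 0.04, -0.25, -0.00044 and -0.33. Among the arrays of low background alone the difference was -0.999, in a fit whose 1 array at 10% is assumed to vary like the other groups. No gene passed between 100% and 10%, with 9 genes at an unadjusted p under 0.05 (5 with 10% replicate 4 turned), or between 100% and 50%, with 11; gene 69 passed in the latter, at 0.95 with an adjusted p of 0.0383, when 50% replicate 2 was left out.

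Whole profiles of the groups were compared as well. Across genes, the mean correlations of pairs of arrays of the same group and of different groups were compared. Those of sample over reference, after subtracting each gene's mean, were both -0.0638, and a permutation test of the group labels gave p = 0.464 (one-sided). After regression of each gene on the dye alone the means were -0.0112 and -0.0769, with p = 0.110 by the same permutation test. A first version of that permutation test, run before it, removed a dye term fitted jointly with the groups and gave 0.0153 and -0.0839, with p = 0.0428. It was replaced because the joint fit leaves the group differences in the values, which alone is no fault in a test of groups. Its dye term was fitted with the real groups and not refitted for permuted labels, which can favour the real groups. Regression on the dye alone can remove group differences, since Cy5 held 3 of 4 samples at 50% and 1 of 4 at 100%. The 3 values are not adjusted for one another. All 3 depend on the direction of 10% replicate 4. With it turned, a version run after these values had been seen, p was 0.0949 for sample over reference (means -0.00707 and -0.0770), 0.0271 after regression on the dye alone (0.0276 and -0.0862) and 0.00663 in the first version (0.0552 and -0.0928). The permutations took no account of the Cy5 background class, which held 3 arrays at 10% and none at 50%. Before each gene's mean is subtracted, 10% replicate 4 correlated with 10% replicates 1 and 2 at -0.581 and -0.323. Turned, it is at 0.581 and 0.323. These arrays are all in the class, whose arrays also resembled each other across groups in Cy5 over Cy3. The permutation tests therefore cannot tell the group from the class. The dye term passed the adjusted threshold in limma for no gene, with 34 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.0627. Among 56 pairs of arrays of the same sample dye, 1 pair, 10% replicate 3 and 50% replicate 1, correlated below -0.3 (r = -0.328); the labels state the dyes and the samples differ in group, so the direction was kept. The direction of 10% replicate 4 was taken from its dye label. With it turned, no gene passed for any concentration against control, and gene 69 passed between 50% and 10%, at -1.01 with an adjusted p of 0.0346.

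**Figure D3:**
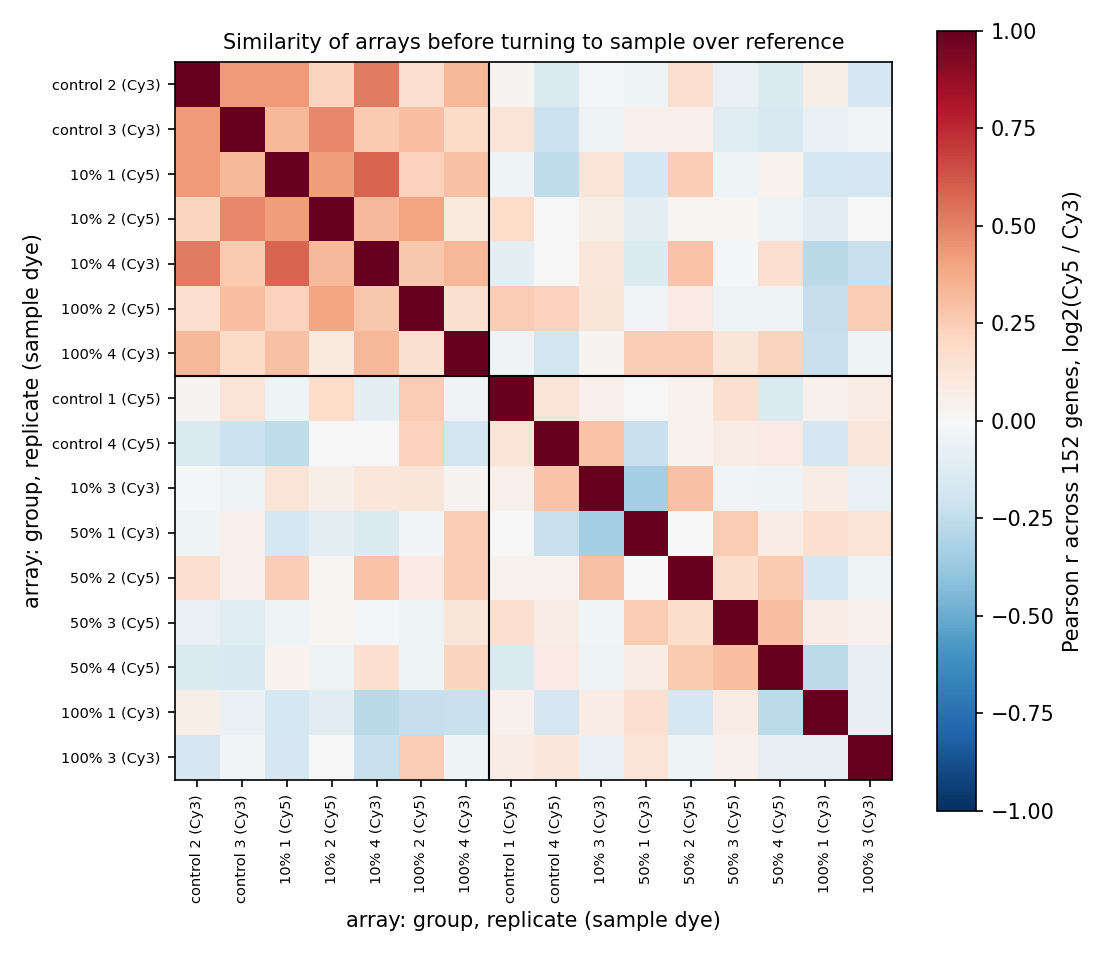
Pearson correlation across 152 genes between arrays of the log2 ratio of Cy5 to Cy3 (colour scale), before turning to sample over reference; both axes list the arrays, the 7 of high Cy5 background first and the 9 others after the lines. The mean correlation was 0.321 among the 7 and 0.00898 over all other pairs.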

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

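The tests on arrays of high Cy5 background, on bright genes and on the direction of 10% replicate 4 were chosen after related values had been seen. Of 52 groups of 4 values, 6 held a value far from the other 3, where chance gives about 2.6. Gene 178 was at 0.48 on control replicate 2, against -0.58 to -0.51 on the other control arrays, and at 0.95 on 100% replicate 1, against 0.03 to 0.19. Gene 144 was at -2.14 on 10% replicate 2, against -0.32 to -0.16. On 100% replicate 2, gene 73 was at -0.86, against -0.16 to -0.04, and gene 77 at -0.65, against -0.03 to 0.04. Gene 129 was at 1.33 on control replicate 1, against -0.07 to 0.09. Gene 69 differed between 50% and 10% effluent by -1.05. The spots named Q, which enter no comparison, exceeded the blank spots in 62.1% of values in Cy3 and 54.0% in Cy5, against 0.391% of the blank spots themselves in each channel.

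Splits of the same arrays, the real one counted among them, gave as many genes at an unadjusted p under 0.05 often enough that chance could not be excluded for any comparison. For 10% against control, 15 of 35 splits gave at least the 11 genes found (28 at most in another split). For 50% the figures were 21 of 35 for 5 genes (17 at most), and for 100% they were 13 of 35 for 6 genes (10 at most). For any concentration 51 of 100 splits gave at least 6 genes (20 at most), and for the trend 42 of 100 gave at least 7 (35 at most). Between 50% and 10%, 9 of 35 gave at least 13 (38 at most), and 4 of 35 gave at least the 1 gene past the adjusted threshold (3 at most). For 100% against 10%, 15 of 35 gave at least 9 (25 at most), and for 100% against 50%, 3 of 35 gave at least 11 (16 at most). In all 8 comparisons the highest count of another split was above the real one. This is likely for the largest of many splits even where the labels carry nothing, so nothing is concluded from it. A structure among the arrays or correlation between genes may also raise these counts, and the splits do not separate them.

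The 7 arrays of high Cy5 background resembled each other in Cy5 over Cy3, with a mean correlation of 0.321 across genes. A bias of the Cy5 channel in these arrays is a candidate explanation: pairs of opposite sample dye and different group, which share neither sample nor direction, correlated at 0.287 on average, above 0 in 9 of 9 pairs, where the 95th percentile of arrays drawn at random was 0.160. The resemblance is thus not confined to pairs of the same dye or group. These 9 pairs are part of the pattern and reuse its 7 arrays, so they are no separate evidence for the bias. Where a control in Cy3 meets a 10% array in Cy5, opposite profiles of the 2 groups would give the same sign. The effluent group as the whole cause of the resemblance would give 1 sign for a pair of groups whichever the dyes. The correlation of sample over reference was therefore taken between 100% arrays and control or 10% arrays of this class, 10% replicate 4 left out. It had the sign of the dyes in 8 of 8 pairs, against 10 of 20 such pairs not both in the class. In the 8 pairs it was 0.190 to 0.398 for the same dye and -0.299 to -0.101 for opposite dyes. This test cannot decide on the group. The controls among these arrays were all in Cy3 and the 10% arrays all in Cy5, so it sets 100% replicate 2 alone against 100% replicate 4. A difference between these 2 pools would give the same signs. The values are also the correlations of the pattern itself turned by the dyes, so they add nothing for the Cy5 bias. The part played by the group stays open. A first version of that test, on 3 pairs of the same group and opposite dyes, gave a mean of -0.353 (between -0.581 and -0.154) and was replaced after it was run because 2 of its pairs held 10% replicate 4.

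The direction of genes 144 and 121 depended on the normalization. An intensity-dependent dye bias is a candidate explanation: with median centring alone, the 7 genes over 2 times the background had a mean Cy5 over Cy3 of the same sign on 15 of 16 arrays, whichever dye held the sample. That mean was 3.28 ± 0.42 (SD, n = 7) on arrays of high Cy5 background and 0.67 ± 0.79 (SD, n = 9) on the others. Genes 37, 121, 131 and 144 are among these 7 genes. The passes of genes 37 and 131 with median centring are therefore open to the same bias. No biological explanation was tested.

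On 10% replicate 4 the deposited ratios run opposite to the dye label. A check fitted group means and a dye term for each Cy5 background class on the 15 other arrays. In the direction of the label and without its dye term, its profile was compared with the 10% mean less the mean of the other groups. The correlation was -0.253. A wrong dye label cannot be told apart from a correct one by this, since the same check gave a correlation above 0 on only 9 of the 15 other arrays.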

How the results depend on the processing

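The alternatives on the Cy5 background class, the turning of 10% replicate 4, the filter on the blank spots and the 2 further uses of the deposited ratios were chosen after seeing the data, and genes 37, 42, 90 and 130 are named after their values were seen. Of 277 counts under alternatives, 252 were 0 and 25 were above 0. Median centring gave 1 gene for any concentration (gene 37), 2 for 10% against control (genes 37 and 131) and, between 50% and 10%, 1 that was not gene 69 but gene 37. Both are among the 7 genes over 2 times the background, so the dye bias of bright genes can enter these calls. The deposited ratios gave 1 gene for 50% against control (gene 73) and, without a dye term, 2 for 10% (genes 42 and 90). The count between 50% and 10% was 0 instead of 1 with background subtracted, with no background correction, with the 7 genes over 2 times the background (gene 69 is not among them), with the deposited ratios (with or without a dye term, or with 10% replicate 4 turned), with array weights, with a trended robust prior, with only the 2 groups in the fit, with the Cy5 background class as a block and with a dye term for each class. Among arrays of low Cy5 background alone the 1 gene was 130, in a fit with 1 array at 10%, which is assumed to vary like the other groups. With each array left out in turn, counts ranged from 0 to 1 for any concentration (1 without 50% replicate 2), 10% against control (1 without control replicate 2), 50% against 10% and 100% against 50% (1 without 50% replicate 2), and were 0 throughout for 50% and 100% against control, the trend and 100% against 10%. Of 436 values of named genes, 431 kept their direction. The genes were chosen by their p in these same arrays, and many alternatives leave out only 1 array. Most of these values could therefore hardly turn, and the count is no measure of replication. The sign turned for gene 144 at 10% with median centring (1.77) and on low-background arrays alone (0.28, with 1 array at 10%), for gene 144 at 100% (1.64 and 1.25) and for gene 121 at 100% with median centring (1.09). The cause was not tested for these changes beyond the dye bias of bright genes. The count of genes at an unadjusted p under 0.05 ranged, with each array left out in turn, from 4 to 15 for any concentration, 4 to 20, 2 to 10 and 2 to 8 for 10%, 50% and 100% against control, and 0 to 8 for the trend. It ranged from 7 to 18 for 50% against 10% (7 without 50% replicate 4, 8 without 10% replicate 2), 6 to 10 for 100% against 10%, and 5 to 18 for 100% against 50% (5 without 100% replicate 2, 7 without 50% replicate 3 or 100% replicate 1, 18 without 50% replicate 1). With median centring it went from 11 to 29 for 10%, 5 to 1 for 50% and 6 to 20 for 100% against control, 6 to 17 for any concentration, 7 to 1 for the trend, 13 to 18 for 50% against 10%, 9 to 2 for 100% against 10% and 11 to 13 for 100% against 50%.

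The replicate numbers were not taken to pair the samples. With the replicate block the count between 50% and 10% stayed 1 (gene 69, adjusted p 0.00882 by limma) and all other counts were 0; 8 of 16 arrays correlated best with their own number, a hint from the data and not from the design. The median of repeated spots, a slide or scan date and the gene list tests with their alternatives were not run. Dim signals limit all of this: the median gene spot was at most 1.16 times its background on any array.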

Other observations

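The 49 genes with 2 spots that were above the blank spots in both channels on at least 8 arrays had a median SD of the log2 ratio over the 16 arrays of 0.46, and the 102 others a median of 0.22. Over the same arrays the 2 spots of a gene correlated at a median of 0.488 and 0.378 in these sets. The sets were formed after the files had been seen, the difference was not tested, and no explanation was tested. The normexp offset, which pulls ratios of dim spots towards 0, can itself lower the SD of the dimmer genes. The SDs of the 2 sets therefore do not show which genes vary more between livers.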
